A study of Mus musculus with 6 samples.

How the data were processed

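Single-cell RNA sequencing was analysed from lung fibroblasts of mice that had been given AdTGF-β1, a treatment the series design describes as establishing lung fibrosis. The cells had been flow-sorted for PDGFRα, a surface receptor of lung fibroblasts. The design sets a mock arm against an arm treated with Spn, described there as acute exacerbation of the fibrosis, at day 15 or day 21 after treatment. The libraries titled PBS were taken as the mock arm, and Spn is kept as an abbreviation because the labels do not spell it out. The 6 libraries fall into 4 groups: PBS at day 15 (n = 1), Spn at day 15 (n = 1), PBS at day 21 (n = 2) and Spn at day 21 (n = 2). The labels do not say whether the libraries of a group came from separate animals or from pools of animals, so p-values measure only the spread between these libraries, which may be technical. The library names neighbour each other within each Spn and PBS pair, and the day 15 pair is numbered apart from both day 21 pairs, so values within each pair are given and day cannot be told apart from a library batch.

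Per the labels' protocols, libraries were made with the 10x Genomics Chromium 3' kit, version 3.1, with a target of 10000 cells per sample. Per the file headers, the deposited matrices hold integer UMI counts written by Cell Ranger 4, with no normalization, and per the submitters' processing notes they were made with Cell Ranger on the mouse build mm10. The aligner settings and the gene annotation release are not given in the sources used here. The deposited count matrices hold every barcode, between 1353876 and 1589096 per library, and no cell calls or cell annotation were among the files used here. The same label text also describes a bulk RNA protocol, which no file analysed here uses.

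Cells were called per library as barcodes with more UMIs than 10% of the 99th percentile of the 10000 largest barcodes and at least 500 UMIs, then 500 or more detected genes and a mitochondrial share of 10% or less. Between 6782 and 12723 cells per library were kept, against the 10000 targeted. Doublets were called with Scrublet as run in scanpy 1.11.5, at an expected 8%. Between 0 and 3 cells per library were marked, under 0.5% of the cells, so the caller did not work and joined cells must be assumed to remain. Cells were clustered on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9), with no batch correction. Serum amyloid A, acute phase, cytokine and interferon genes were kept out of the clustering. Each of the 18 clusters was named only from marker sets fixed before the data were examined, where at least 3 markers were detected in 10% or more of its cells at 2-fold or more over the other cells, and 7 fibroblast clusters stayed unnamed. One cluster carried smooth muscle and peribronchial fibroblast markers in equal number. A cluster with macrophage or monocyte markers was called mixed immune because B or plasma cell markers were also among its 10 leading genes. The endothelial-like cluster held 9 cells in all and was left out of the share tests after its size was seen.

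For testing, UMI counts were summed per library over the fibroblast-like cells, that is the alveolar, adventitial, fibrotic and unnamed fibroblast clusters together, without smooth muscle-like, mesothelial-like and proliferating cells. These sums held 35931437 to 46879027 UMIs per library. CPM values are UMIs scaled to a sum of 1000000 per library. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The day 21 comparison used the 4 day 21 libraries and had 2 residual degrees of freedom. The comparison over both days used all 6 libraries with day and treatment as additive terms and had 3. The day term of that fit gave the comparison of day 21 with day 15, and the same fit was run within each fibroblast class that had 50 or more cells in every library. DESeq2 1.42.0 was run as an alternative. An edgeR fit with a day by treatment term was added after the results were seen. It takes its residual spread from the day 21 replicates alone and assumes that the lone day 15 libraries vary alike.

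The 25 gene lists were fixed before the data were examined: serum amyloid A and acute phase; cytokines and chemokines; NF-kB, IL-1 and IL-17 targets; interferon response; antigen presentation; complement; extracellular matrix; myofibroblast and fibrotic fibroblast; matrix proteases and inhibitors; alveolar fibroblast; adventitial fibroblast; TGF-beta targets; hypoxia and glycolysis; cell cycle; dissociation and immediate early genes; the unfolded protein response; and markers of neutrophils, macrophages and monocytes, lymphocytes, alveolar epithelium, airway epithelium, endothelium, mesothelium, pericytes and smooth muscle, and erythrocytes and platelets. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with a correlation estimated from the libraries. At day 15, where each group has 1 library, no test was made. Ratios of CPM are given with exact 95% intervals that cover counting error only, and the median of each list was placed among 10000 random lists of the same size matched on mean expression. Ratios with a count of 0 in one library were computed against a floor of 3 UMIs.

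Shares of cells per class were compared with exact two-sided permutation tests. With 3 libraries against 3 the smallest possible p is 0.1, and with 2 against 2 it is 0.333. Shares of cells with a UMI were computed after thinning every cell to 1500 UMIs, leaving out shallower cells, with exact Clopper-Pearson intervals. Barcodes with 1 to 100 UMIs served as the profile of free RNA. Gene coordinates are from GENCODE mouse release 21 (GRCm38, the assembly called mm10), in which 32158 of the 32285 gene identifiers in the files were found. Clustering and tables used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0, and plots used matplotlib 3.10.9.

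The gene test was tested on simulated data before it was run, with counts drawn from the means and sizes of the real libraries at a dispersion of 0.02 and 200 genes changed. For the day 21 comparison, 81% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 5 false calls among 14450 unchanged genes. For both days together, 96% and 100% were recovered, with 11 false calls among 15095. For the day by treatment term, 22% and 99% were recovered, with 4 false calls among 15105. No unmoved list passed in either simulated comparison, and the 1 moved list was found in each. The draw set no correlation between genes. For the real libraries of day 21, estimated correlations ranged from -0.264 (mesothelium) to 0.853 (antigen presentation). Over both days, a split of the libraries other than the real one also passed 15 lists. The simulation therefore cannot show that false list calls are controlled. Its gene recovery holds for a dispersion of 0.02 only, and Saa3 at day 21 (log2 fold change 4.91) did not pass in edgeR.

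Named genes followed a rule fixed before the data were examined. Per tested comparison it takes the 10 largest changes in each direction among genes past the threshold with a mean CPM of 10 or more and with each Spn library on the same side of the PBS libraries of its day. Where fewer pass, it adds the genes of smallest p up to 5 in a direction, stated not to pass. Saa1, Saa2, Saa3, Saa4, Pdgfra, Col1a1, Acta2 and Cthrc1 are always named, with up to 4 genes of smallest p per list. After the values were seen, this was held to 3 per list, and to 1 per list of other cell types. Some genes that this would name are not reported here. Within the alveolar and adventitial classes, the genes named were chosen after their values were seen. At day 15 the rule takes the 10 largest and 10 smallest CPM ratios among genes with a CPM of 50 or more in the higher library and 20 or more UMIs in all. Predicted genes and ribosomal protein and mitochondrial genes are not named by size. H2-Q6 and H2-Q7, Saa1 and Saa2, the Serpina3 genes and the Ifi200 genes have near-identical family members, between which 3' reads may be split, so their separate values are uncertain.

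Alternatives fixed in advance were DESeq2, DESeq2-style (RLE) size factors, no low-count filter, the sample number as a block, leaving out each library, keeping called doublets, at least 2000 UMIs per cell, a mitochondrial share of 5% or less, cells taken by detected genes, all called cells, Leiden resolution 0.5, a CPM minimum of 50 in place of 20 at day 15, and a prior count of 0.5 for lists. Removing the highest 8% of doublet scores was added after the data were seen.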

Results

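Transcripts of single PDGFRα-sorted lung fibroblasts were counted in 6 libraries from mice with AdTGF-β1-induced lung fibrosis, 3 from mice given PBS and 3 from mice given Spn, at day 15 (1 library each) and day 21 (2 libraries each). The libraries held 40494058 UMIs for PBS and 53425252 for Spn at day 15. At day 21 they held 41608772 and 43707294 UMIs for PBS samples 1 and 2 and 50857091 and 50780646 for Spn samples 1 and 2. From these, 7350, 6782, 7085, 11287, 7677 and 12723 cells were called in the same order, with medians of 4708, 6337.5, 5102, 3226, 5687 and 3226 UMIs per cell. Sample 1 and sample 2 at day 21 thus differed in depth per cell, as did Spn and PBS at day 15. The median mitochondrial share was 1.308% in the day 15 Spn library against 2.36% with PBS at day 15 and 2.126% to 3.031% at day 21. Fibroblast-like cells made up 94.77% to 97.47% of cells in each library. Counting intervals throughout cover counting error only.

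The series title names serum amyloid A, an acute phase protein, as a product of lung fibroblasts in exacerbated fibrosis. Saa3, the family member known from fibroblasts and macrophages, was examined first. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand, mm10) was higher in each Spn library than in the PBS libraries of its day. In fibroblast-like cells it reached 60949 CPM with Spn against 265 with PBS at day 15. At day 21 it reached 1340 and 5810 CPM with Spn against 107 and 135 with PBS. At day 15 this made Saa3 230-fold higher (95% counting interval 225 to 235, 1 library per group). At day 21 the log2 difference within pairs was 3.65 in sample 1 and 5.43 in sample 2. Lcn2, which encodes lipocalin-2, a protein that withholds iron from bacteria, moved from 83.7 to 18288 CPM at day 15 and from 12.3 and 25.8 to 286 and 1564 CPM at day 21. The neighbouring serum amyloid genes on chromosome 7 were expressed far lower, with Saa1 at 578 CPM, Saa2 at 84.0 CPM and Saa4 at 25.02 CPM in the day 15 Spn library. Over both days the edgeR log2 fold change of Saa3 was 5.92 ± 1.02 (SE, n = 3 per group), with an adjusted p of 0.193 that did not pass the threshold. DESeq2 gave 5.92 with an adjusted p of 4.6e-06. The edgeR fit without Spn sample 1 of day 21 gave 6.82 with an adjusted p of 0.0358. Leaving out any other library gave 4.91 to 6.31 with adjusted p-values of 0.109 to 0.636.

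After thinning to 1500 UMIs, 86.9% of fibroblast-like cells (95% interval 86.1 to 87.7) held a Saa3 UMI in the day 15 Spn library, against 5.45% (4.93 to 6.01) with PBS. At day 21 the shares were 14.7% (13.9 to 15.5) and 31.7% (30.8 to 32.5) with Spn, against 2.32% (1.98 to 2.71) and 3.08% (2.75 to 3.42) with PBS. The unthinned shares were 92.8% and 8.06% at day 15, 20.4% and 37.6% with Spn at day 21, and 3.64% and 3.89% with PBS. Thinning left out between 0 and 592 cells per library. Mesothelial-like cells, which line the lung surface, held Saa3 in 53.4% of 58 and in 77 of 100 cells with Spn at day 21. With PBS it was held by 0 of 27 and 0 of 23. Adventitial fibroblast-like cells, the fibroblasts around vessels and airways, held it in 30.9% and 56.3% with Spn, and alveolar fibroblast-like cells in 3.67% and 10.6%. In the mixed immune cluster the shares were 74.5% with Spn at day 15 and 10.9% and 34.1% with Spn at day 21. The share of fibroblast-like cells in Spn sample 2 of day 21 thus did not lie above that of the immune cluster. That cluster had median depths of 9440.5, 6826 and 4339 UMIs per cell, against 6298, 5680 and 3191 in fibroblast-like cells. Of its cells 97.6% also held a Col1a2 UMI, 81.9% a Pdgfra UMI and 14.95% a UMI of the leukocyte gene Ptprc. Its values therefore do not describe immune cells alone.

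**Figure D1:**
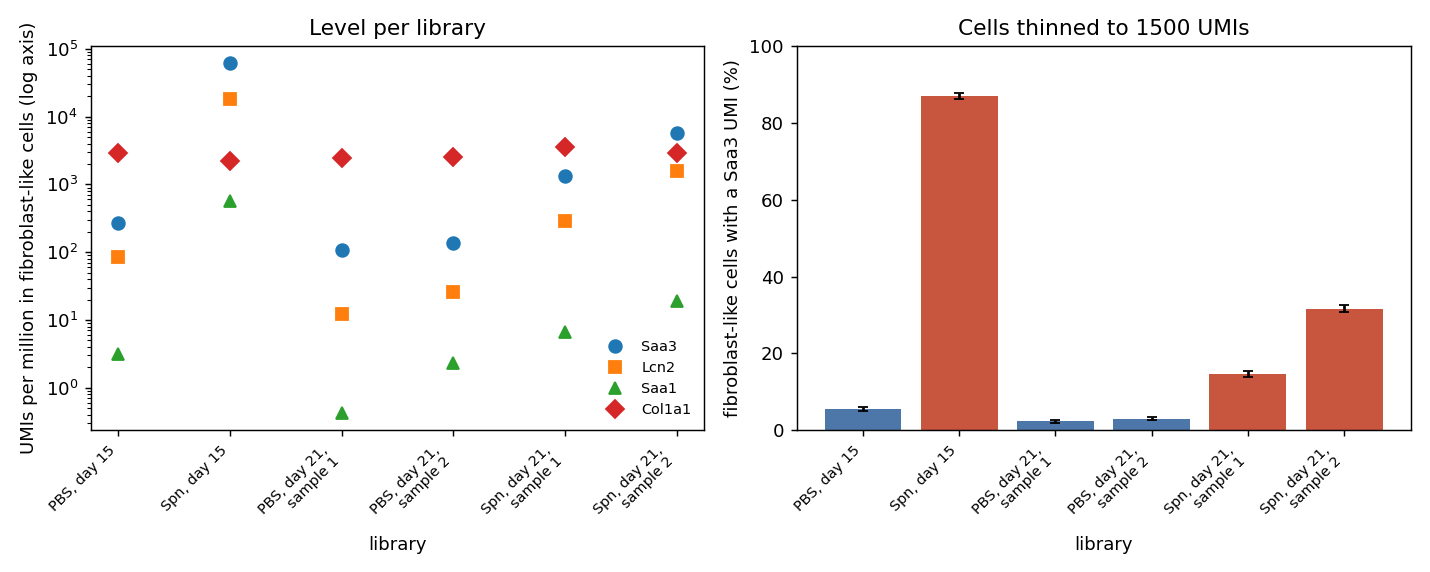
The left panel plots CPM of Saa3, Lcn2, Saa1 and Col1a1 in fibroblast-like cells of each library on a log axis, and the right panel the percentage of cells with a Saa3 UMI after thinning to 1500 UMIs, with PBS libraries in blue, Spn libraries in red and bars for exact 95% intervals. Saa3 was at 60949 CPM in the day 15 Spn library and between 107 and 265 CPM in the PBS libraries, while the collagen gene Col1a1 stayed between 2219 and 3585 CPM.

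At day 15, the fibroblast-like cells of the Spn library carried an acute phase, chemokine and interferon programme at levels far above PBS and fewer transcripts of alveolar fibroblast genes. The largest ratios among genes with 50 CPM or more belonged to Saa2 (335-fold), Csf3 (267-fold), Saa3 (230-fold), Lcn2 (218-fold), Saa1 (184-fold), Ptx3 (135-fold), Cxcl5 (107-fold), Cxcl13 (89.4-fold) and Serpina3m (58.2-fold). Ifi202b, with 0 UMIs in the PBS library, stood ahead of them, 1694-fold higher against a floor of 3 UMIs (counting interval from 1377). Csf3 encodes the neutrophil growth factor G-CSF, Cxcl5 and Cxcl13 attract neutrophils and B cells, and Ptx3 is a secreted pattern recognition protein. The lowest ratios belonged to the carboxypeptidase gene Cpm (16.8-fold lower, counting interval 14.2 to 19.9), the sodium channel gene Scn3a (11.6-fold), Nnat (10.2-fold) and the integrin gene Itga8 (8.38-fold). They were followed by Scube2 (7.99-fold), the contractile gene Tagln (7.63-fold), St8sia2 (7.40-fold), Thbd (7.24-fold), Mamdc2 (7.20-fold) and the procollagen enhancer gene Pcolce2 (7.15-fold). In all, 327 of 6420 genes with 20 CPM or more were at least 2-fold higher and 992 at least 2-fold lower. With TMM factors the split was 668 higher and 374 lower. The median log2 ratio of all genes moved from -0.35 to 0.13. For comparison, the replicate libraries of day 21 differed 2-fold at 4 genes between both PBS samples and at 33 between both Spn samples. Day 15 itself has no replicate and no test. Its Spn library may also hold cells of mice of differing genotype, or be mixed or mislabelled, as described in a later part. All day 15 values, also those of lists and clusters, carry this limit.

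The serum amyloid A and acute phase list had a median log2 ratio at day 15 of 4.44, the neutrophil marker list of 3.60 and the interferon response list of 2.74. The cytokine and chemokine list followed at 1.76 and the antigen presentation list at 1.16. Each of the 5 lay at the 100th percentile of matched random lists. The neutrophil list contains Lcn2, which fibroblasts also express. Of the 27 measured interferon response genes 25 were at least 2-fold higher. So were 11 of 14 acute phase genes, 16 of 22 cytokine and chemokine genes and 11 of 20 antigen presentation genes. The unfolded protein response (0.56), hypoxia and glycolysis (0.37), macrophage and monocyte (0.36), NF-kB, IL-1 and IL-17 (0.34) and cell cycle (0.24) lists lay above the 99.8th percentile of random lists. The lymphocyte list (1.01, 3 genes) lay at the 98.95th. Complement (0.18) lay at the 91.6th percentile. At the other end, the alveolar fibroblast list had a median of -1.97, with 16 of 20 genes at least 2-fold lower. The TGF-beta target list had -1.03 with 11 of 20 lower and the alveolar epithelial list -1.55 with 9 of 13 lower. These 3 lay below the 0.2nd percentile. The myofibroblast and fibrotic fibroblast list (-0.75, 1.5th percentile), the extracellular matrix list (-0.64, 2.3rd), the dissociation and immediate early list (-0.66, 1.9th) and the pericyte and smooth muscle list (-1.06, 2.2nd) lay low. The remaining lists lay inside their random ranges, namely adventitial fibroblast (-0.28), matrix proteases and inhibitors (-0.38), airway epithelial (0.01), endothelial (-0.19) and mesothelial (-0.03). Medians with TMM factors were 0.42 higher throughout, which turned the adventitial, protease, endothelial and mesothelial lists to above 0 and left the direction of the other lists.

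At day 21, where both arms had replicates, Rnd1 rose with Spn. Most genes of the acute phase, chemokine, interferon response and antigen presentation lists had log2 fold changes above 0. None of them passed the threshold one by one in edgeR, while DESeq2 called several. Rnd1 (ENSMUSG00000054855, chromosome 15, 98663421 to 98677461, minus strand, mm10) encodes a small GTPase that lacks GTP hydrolysis. It stood at 30.7 and 29.9 CPM with Spn against 10.9 and 9.51 CPM with PBS. Its log2 fold change was 1.57 ± 0.097 (SE, n = 2 per group, edgeR adjusted p = 0.0118). The genes of smallest p after it were higher with Spn but did not pass in edgeR. They were Postn, a matrix protein of fibrotic fibroblasts (1.28 ± 0.11, edgeR adjusted p = 0.0510), Rspo3, a Wnt pathway enhancer (1.82 ± 0.17), Parm1 (2.42 ± 0.27) and the interferon-inducible Ifi205 (1.48 ± 0.18). Lower with Spn, also without passing in edgeR, were Nnat (-0.82 ± 0.099), Net1 (-1.02 ± 0.12), the potassium channel gene Kcnk2 (-0.77 ± 0.11), Mustn1 (-0.73 ± 0.11) and Syn3 (-0.76 ± 0.12). DESeq2 called all 9 of these genes, with adjusted p-values from 9.0e-19 (Parm1) to 6.4e-04 (Mustn1). Saa3 had a log2 fold change of 4.91 ± 0.71 with an edgeR adjusted p of 0.117, and Lcn2 of 5.62 ± 0.88 with 0.136. Both passed without PBS sample 1 (edgeR adjusted p = 1.1e-07 for Saa3 and 5.4e-08 for Lcn2), without Spn sample 1 (4.8e-06 and 2.7e-05) and without Spn sample 2 (8.5e-04 and 0.00525). Without PBS sample 2 neither passed (edgeR, 0.170 and 0.156). Both passed with DESeq2 (adjusted p = 8.6e-05 and 3.0e-04). Both also passed with the sample number as a block in edgeR (adjusted p = 0.0294 and 0.00907), a pairing the labels do not establish. With that block Postn (edgeR adjusted p = 0.0120), Rspo3 (0.00907), Parm1 (0.0106), Ifi205 (0.0422), Nnat (0.0271), Net1 (0.0186), Kcnk2 (0.0450) and Mustn1 (0.0369) passed as well. The sorting gene Pdgfra (-0.13 ± 0.13), the collagen gene Col1a1 (0.35 ± 0.18), the myofibroblast actin Acta2 (0.02 ± 0.20) and the fibrotic fibroblast gene Cthrc1 (1.03 ± 0.19) did not pass either, with edgeR adjusted p-values of 0.951, 0.760, 0.992 and 0.180. Of these 4, DESeq2 called Cthrc1 (adjusted p = 0.0189).

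Of 14809 genes tested at day 21, edgeR thus called 1 gene, with 1111 at an unadjusted p under 0.05, and DESeq2 called 203. Of these 165 were higher with Spn. With the sample number as a block edgeR called 55, 46 higher and 9 lower. Within pairs, only genes with 20 CPM or more in the higher library were compared. Of 6436 such genes, 15 were at least 2-fold higher and 1 lower in sample 1, against 96 and 8 of 6258 in sample 2. The count of calls rested on single libraries. It was 318 without PBS sample 1, 339 without Spn sample 1, 24 without Spn sample 2 and 4 without PBS sample 2. Without the low-count filter Rnd1 itself had an edgeR adjusted p of 0.0697.

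Of the 24 gene lists measured at day 21, 13 passed camera (limma) with the preset correlation, 12 higher and 1 lower with Spn. None passed with a correlation estimated from these 4 libraries. Without PBS sample 1 the count was 8. The antigen presentation list was higher (median log2 fold change 0.92, adjusted p = 3.6e-14, and adjusted p = 0.567 with an estimated correlation). All 20 members lay above 0, with 18 past the threshold when adjusted over the list alone. H2-Q7 (1.59 ± 0.21), Nlrc5, the regulator of class I genes (1.36 ± 0.22), and the peptide transporter gene Tap1 (1.09 ± 0.19) led it. The interferon response list was higher (0.75, adjusted p = 2.1e-13, and adjusted p = 0.567 with an estimated correlation). Of its 27 members 21 were past the threshold adjusted over the list alone, among them Gbp4 (1.74 ± 0.23), Rsad2 (1.47 ± 0.24) and Ifi44 (1.54 ± 0.28). The serum amyloid A and acute phase list (2.39, adjusted p = 3.3e-11, and adjusted p = 0.567 with an estimated correlation) had 11 of 12 members past the threshold adjusted over the list alone. Saa1 stood at 3.20 ± 0.73, Saa2 at 6.70 ± 1.49, Saa4 at 5.70 ± 0.94 and the metalloreductase Steap4 at 1.09 ± 0.16. Saa2 lay at 0.46 and 2.81 CPM with Spn against 0.027 and 0 CPM with PBS. Saa4 lay at 1.01 and 3.30 against 0.027 and 0.051 CPM. The sizes of these 2 changes rest on few UMIs and cannot be ranked against that of Saa3. The cytokine and chemokine list (0.92, adjusted p = 7.4e-09, and adjusted p = 0.567 with an estimated correlation) had 13 of 21. They held the neutrophil attractants Cxcl2 (2.43 ± 0.33) and Cxcl5 (5.42 ± 0.76) and the T cell attractant Cxcl9 (1.75 ± 0.31). The complement list (0.42, adjusted p = 1.9e-06, and adjusted p = 0.567 with an estimated correlation) had 3 of 11. Its leading members were Cfb (1.21 ± 0.19), C3 (0.97 ± 0.20) and C6 (0.94 ± 0.20). No member of these lists passed the threshold adjusted over all genes in edgeR without the block. DESeq2 called members of each, such as H2-Q7 (adjusted p = 3.4e-14), Gbp4 (1.7e-11), Steap4 (1.6e-08), Cxcl5 (2.7e-05) and Cfb (1.7e-08). With the block Saa1 (edgeR adjusted p = 0.00768), Saa2 (0.0422), Saa4 (0.0116), Steap4 (0.0271), Cxcl2 (0.00122), Cxcl5 (0.00558), Gbp4 (0.0437) and H2-Q7 (0.0472) were among those that did. DESeq2 did not call Saa1 (adjusted p = 0.418) or Saa2 (0.0587).

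Fibrosis genes were divided at day 21. The myofibroblast and fibrotic fibroblast list was higher with Spn (median 0.18, limma adjusted p = 0.00680, and adjusted p = 0.662 with an estimated correlation). Postn, Adam12 (2.03 ± 0.35) and Cthrc1 were among 5 members higher and 2 lower when adjusted over the list alone. Over all genes, Adam12 passed with the sample number as a block (edgeR adjusted p = 0.0442), as did Mmp13 below (0.00907), which DESeq2 did not call (0.104). Both genes were sparse. Adam12 stood at 1.93 and 2.62 CPM with Spn against 0.426 and 0.683 CPM with PBS. Mmp13 stood at 5.54 and 0.498 against 0.053 and 0 CPM, so its rise came mostly from Spn sample 1. The TGF-beta target list was lower (-0.14, adjusted p = 0.00244, and adjusted p = 0.567 with an estimated correlation). Bhlhe40 (-0.51 ± 0.11) and Id1 (-0.57 ± 0.18) were among its leading members, with 1 member lower when adjusted over the list alone. The extracellular matrix list did not pass (0.08, limma adjusted p = 0.251), with Col12a1 at -0.64 ± 0.14, P4ha2 at 0.45 ± 0.096 and Col5a1 at 0.27 ± 0.11. Neither did the matrix protease list (adjusted p = 0.884; Mmp23 0.43 ± 0.092, Mmp13 6.67 ± 1.6) or the alveolar fibroblast list (adjusted p = 0.310; Inmt -0.51 ± 0.16, Mfap4 0.41 ± 0.17, Fgf10 -0.19 ± 0.10). The adventitial fibroblast list did not pass (limma adjusted p = 0.455; the alarmin gene Il33 1.22 ± 0.24, Ly6a 0.73 ± 0.20, Ccl11 0.53 ± 0.19).

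The unfolded protein response list was higher at day 21 (median 0.18, limma adjusted p = 0.00125, and adjusted p = 0.567 with an estimated correlation). Manf (0.65 ± 0.15), Sdf2l1 (0.43 ± 0.11) and Creld2 (0.52 ± 0.16) led it, with 0 of 16 members past the threshold adjusted over the list alone. The cell cycle list was higher by a small margin (0.10, limma adjusted p = 0.0464, and adjusted p = 0.567 with an estimated correlation; Ube2c 1.40 ± 0.37, Cdk1 1.26 ± 0.38). So was the NF-kB, IL-1 and IL-17 list (0.14, limma adjusted p = 0.0464, and adjusted p = 0.662 with an estimated correlation; Traf1 0.79 ± 0.19, Sod2 0.89 ± 0.29, Tnfaip2 -0.43 ± 0.16). Both had 0 members past the threshold adjusted over the list alone. Neither list passed with the sample number as a block (limma adjusted p = 0.0816 for cell cycle and 0.0688 for NF-kB, IL-1 and IL-17). The hypoxia and glycolysis list (adjusted p = 0.836, Ndrg1 0.36 ± 0.12) and the dissociation and immediate early list (adjusted p = 0.169, Atf3 -0.44 ± 0.14) did not pass camera in limma. Markers of other cell types moved beside these lists. By camera in limma, the neutrophil list (median 1.55, adjusted p = 0.00208, and adjusted p = 0.567 with an estimated correlation) and the lymphocyte list (1.17, adjusted p = 2.4e-04, and adjusted p = 0.567 with an estimated correlation; Ighm 1.44 ± 0.18) were higher with Spn. The macrophage and monocyte list was higher as well (0.41, limma adjusted p = 0.00705, and adjusted p = 0.662 with an estimated correlation; Plac8 1.37 ± 0.34). These 3 lists had 3 of 6, 3 of 4 and 0 of 14 members past the threshold adjusted over the list alone. The lists of alveolar epithelium (adjusted p = 0.251, Cldn18 -0.94 ± 0.35), airway epithelium (0.338, Scgb3a2 -3.07 ± 0.97, from 4.93 CPM in PBS sample 1 against 0.480 CPM or less in the other day 21 libraries) and endothelium (0.675, Ramp2 0.55 ± 0.15) did not pass in limma. Neither did those of mesothelium (0.169, Rspo1 0.62 ± 0.16) and pericytes and smooth muscle (0.836, Mustn1). Erythrocyte and platelet markers were too few at day 21 to be tested as a list (Pf4 0.52 ± 0.33).

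**Figure D2:**
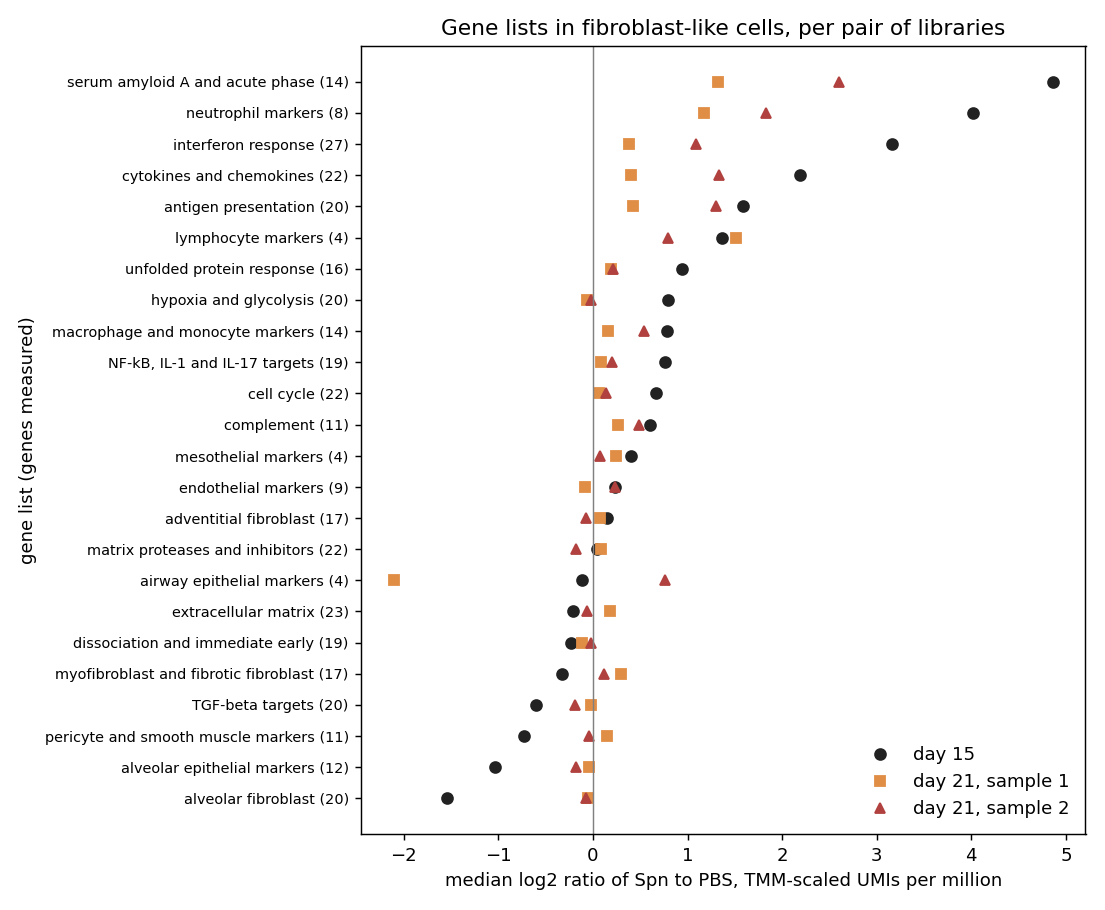
Each row gives the median log2 ratio of Spn to PBS over the genes of a list measured in fibroblast-like cells, on TMM-scaled CPM, for the day 15 pair (circles) and day 21 samples 1 (squares) and 2 (triangles), with the number of genes in brackets and 1 library per arm in each pair. The acute phase list lies at 4.86, 1.32 and 2.60 and the interferon list at 3.16, 0.38 and 1.09, while the alveolar fibroblast list lies at -1.54 at day 15 and at -0.05 and -0.08 at day 21.

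Across both days, Rspo3, Parm1, the antigen presentation gene H2-Q6 and the serpin gene Serpina3g were higher in each of the 3 Spn libraries than in the PBS libraries of the same day. Net1, Maff, Mustn1 and Col12a1 were lower in each. Rspo3 stood at 22.2 CPM against 7.38 CPM at day 15. At day 21 it stood at 17.0 and 21.8 against 5.54 and 5.49 CPM (log2 fold change 1.88 ± 0.15, SE, n = 3 per group, edgeR adjusted p = 0.0802). Parm1 had a log2 fold change of 2.35 ± 0.23, H2-Q6 of 1.82 ± 0.21 and Serpina3g of 1.70 ± 0.20. Net1 had one of -1.30 ± 0.20, Maff of -0.70 ± 0.13, Mustn1 of -0.997 ± 0.19, Col12a1 of -0.72 ± 0.14 and Shisal1 of -0.64 ± 0.13. Ifi202b (14.2 ± 0.73) came from the day 15 Spn library, with 6630 UMIs there, 2 in Spn sample 2 of day 21 and 0 in the other libraries. None of these passed in edgeR. DESeq2 called all of them but Ifi202b, with adjusted p-values from 8.3e-17 (Rspo3) to 0.0236 (Shisal1). Of 15678 genes edgeR called 0, with 1685 at an unadjusted p under 0.05, and DESeq2 called 256. Of these 216 were higher with Spn. Without Spn sample 1 of day 21 edgeR called 56, without the day 15 PBS library 1, and without the day 15 Spn library 1. The other genes followed throughout were Saa1 (4.74 ± 1.26), Saa2 (8.59 ± 1.04), Saa4 (6.02 ± 0.63), Pdgfra (-0.08 ± 0.15), Col1a1 (0.24 ± 0.20), Acta2 (-0.34 ± 0.27) and Cthrc1 (0.50 ± 0.33). They did not pass in edgeR, but Saa4 did with the sample number as a block (edgeR adjusted p = 0.0254). DESeq2 called Saa1 (adjusted p = 0.0432), Saa2 (1.7e-06) and Saa4 (1.1e-16). Saa2 and Saa4 stood at 0.473 CPM or less in each PBS library, so the sizes of their changes are uncertain. Acta2 turned to 0.02 without the day 15 PBS library and to 0.02 without the day 15 Spn library. In either fit the day term takes up the remaining day 15 library, so the Spn effect rests on day 21 alone. Both fits thus repeat the day 21 comparison, where Acta2 stood at 0.02, and are not separate checks.

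Over both days 15 of 25 lists passed camera (limma) with the preset correlation, 12 higher and 3 lower, and 0 with an estimated correlation. Without the PBS or without the Spn library of day 15, 10 lists were higher and 1 was lower. In both of those fits the Spn effect rests on day 21 alone. Leaving out a day 21 library gave 13 to 15. The antigen presentation list was higher (median 0.98, adjusted p = 3.9e-14, and adjusted p = 0.473 with an estimated correlation, 17 of 20 past the threshold adjusted over the list alone). So were the interferon response list (1.52, adjusted p = 3.0e-13, and adjusted p = 0.473 with an estimated correlation, 13 of 27) and the cytokine and chemokine list (1.39, adjusted p = 9.1e-12, and adjusted p = 0.473 with an estimated correlation, 16 of 22). The acute phase list was higher too (3.44, limma adjusted p = 2.2e-11, and adjusted p = 0.473 with an estimated correlation, 12 of 14). H2-K1 (1.14 ± 0.21), Iigp1 (1.19 ± 0.25), Csf3 (7.64 ± 1.03) and Steap4 (1.32 ± 0.20) were among their leading members. Complement (0.50, limma adjusted p = 9.7e-05, and adjusted p = 0.473 with an estimated correlation, 1 of 11 adjusted over the list alone) was higher. The unfolded protein response was higher as well (0.44, limma adjusted p = 9.0e-06, and adjusted p = 0.473 with an estimated correlation, 0 of 17). C3 stood at 1.08 ± 0.21 and Manf at 0.86 ± 0.19. Lower lists were alveolar fibroblast (-0.54, limma adjusted p = 0.00103, and adjusted p = 0.558 with an estimated correlation) and TGF-beta targets (-0.28, adjusted p = 6.1e-04, and adjusted p = 0.473 with an estimated correlation). Alveolar epithelial markers were lower as well (-0.41, limma adjusted p = 0.0109, and adjusted p = 0.558 with an estimated correlation), and each of the 3 lists had 0 members past the threshold adjusted over the list alone. The alveolar fibroblast list lay at -1.54 at day 15 but at -0.05 and -0.08 at day 21 on TMM-scaled CPM. Inmt (-0.89 ± 0.28), Slc38a5 (-0.77 ± 0.33), Bhlhe40 (-0.63 ± 0.14) and Ccn2 (-0.87 ± 0.26) were among the leading members of the lower lists.

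The remaining lists that passed over both days in limma were higher. They were NF-kB, IL-1 and IL-17 targets (median 0.39, adjusted p = 0.00233, and adjusted p = 0.513 with an estimated correlation) and hypoxia and glycolysis (0.35, adjusted p = 0.0475, and adjusted p = 0.558 with an estimated correlation). The latter did not pass with the sample number as a block (limma adjusted p = 0.0565). Cell cycle genes were among them (0.33, limma adjusted p = 0.00708, and adjusted p = 0.473 with an estimated correlation). So were the neutrophil (2.53, limma adjusted p = 3.1e-04, and adjusted p = 0.473 with an estimated correlation), macrophage and monocyte (0.41, adjusted p = 0.0116, and adjusted p = 0.513 with an estimated correlation) and lymphocyte markers (1.04, adjusted p = 0.00177, and adjusted p = 0.473 with an estimated correlation). Of these, 5 of 8 neutrophil and 3 of 5 lymphocyte markers passed when adjusted over the list alone, and 0 members of the other lists did. The lists of extracellular matrix (limma adjusted p = 0.833), myofibroblast and fibrotic fibroblast (0.239), matrix proteases (0.716) and adventitial fibroblast (0.652) did not pass. Neither did those of dissociation and immediate early genes (0.278), airway epithelium (0.833), endothelium (0.652), mesothelium (0.278), pericytes and smooth muscle (0.521) and erythrocytes and platelets (0.833). Across 6419 genes, the log2 ratio at day 15 correlated with the edgeR log2 fold change at day 21 (Pearson r = 0.666, Spearman correlation 0.529; genes are not independent replicates). The direction was shared by 4247 of them (66.2%). Day 15 ratios here were scaled to total UMIs, with a median of -0.349 against 0.001 at day 21. With TMM factors the day 15 median was 0.127, so the shared directions and 2-fold sets rest in part on the scaling. Of 326 genes at least 2-fold higher at day 15, 306 (93.9%) were higher at day 21, 274 of them in both samples. Of 992 at least 2-fold lower, 783 (78.9%) were lower at day 21, 547 of them in both samples. The 992 genes had a median edgeR log2 fold change of -0.109 at day 21 and a Pearson r of 0.207 within the set.

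Between day 21 and day 15, immunoglobulin light chain transcripts of Igkc, a product of B and plasma cells, were at 16.8 to 66.3 CPM at day 21 against 6.96 and 18.3 CPM at day 15. The mitochondrial tRNA ligase gene Lars2 was at 140 to 243 against 97.8 and 64.0 CPM. Neither passed in edgeR (log2 fold change 1.55 ± 0.28 and 1.08 ± 0.17), nor did Lrrc8d (0.67 ± 0.13), Hivep2 (0.80 ± 0.15) or Shisal1 (0.72 ± 0.14). Lower at day 21 without passing in edgeR were Saa2 (-6.03 ± 0.74), Sft2d1 (-1.03 ± 0.13), Rnaset2a (-1.54 ± 0.21) and Errfi1 (-0.89 ± 0.13). DESeq2 called all 9 of these genes, with adjusted p-values from 8.0e-06 (Rnaset2a) to 0.0259 (Shisal1). Of 15678 genes edgeR called 3, all lower at day 21, with 2549 at an unadjusted p under 0.05. DESeq2 called 137. The 3 were Ifi202b (-12.7 ± 0.47, edgeR adjusted p = 0.0343), Calcr (-6.35 ± 0.51, 0.0438) and Mt3 (-5.98 ± 0.50, 0.0438). Calcr and Mt3 lie below 2 CPM in each library and, outside the rule, were chosen after their values were seen. All 3 stand out in the day 15 Spn library rather than on day 15 as such. Day coincides with the library numbering. The count was 5293 without the day 15 PBS library, 0 without the day 15 Spn library, 0 without Spn sample 2, 1 without PBS sample 1 and 1 without PBS sample 2 of day 21.

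The shares of cell classes were compared between arms, and 0 of the tests passed. Fibrotic fibroblast-like cells, led by Nnat, Ltbp2 and Net1, made up 5.42%, 5.45% and 7.17% of cells in the PBS libraries of day 15 and day 21 and 0.147%, 1.17% and 0.519% in the Spn libraries (mean 6.01 ± 1.00% against 0.613 ± 0.519%, SD, n = 3, exact permutation p = 0.1). Their name rests on 3 of 10 markers (Col12a1, Tnc and Ltbp2), with a mean log2 fold over the set of 0.18 against 0.327 for the smooth muscle set. Alveolar fibroblast-like cells made up 25.7%, 24.8% and 19.5% with PBS and 4.38%, 17.1% and 11.1% with Spn (mean 23.3 ± 3.32% against 10.9 ± 6.34%, exact permutation p = 0.1). At Leiden resolution 0.5 the direction turned in sample 2 of day 21. There the alveolar-named clusters held 4740 and 740 of 12723 cells with Spn, against 2294 and 1489 of 11287 with PBS. In the other pairs the share stayed lower with Spn. Adventitial fibroblast-like cells were at 10.9%, 14.1% and 11.2% with PBS and 28.7%, 16.2% and 12.4% with Spn (exact permutation p = 0.2). The difference of 7.04 percentage points became 2.24 without the day 15 Spn library and -1.31 at Leiden resolution 0.5. In the day 15 Spn library 25.9% of cells lay in an adventitial-like cluster that held 0.55% or less of any other library and was led by Ly6c1, Cxcl13, Ly6a, Ccl8 and Isg15. Ifi202b was also among its leading genes, at rank 8. Its name rests on 4 of 10 markers (Pi16, Ly6c1, Ccl11 and Serpinf1), with a mean log2 fold over the set of 0.59. The other adventitial-like cluster had 8 of 10 markers and a mean of 1.96. A further 53.6% of the cells of the day 15 Spn library lay in an unnamed fibroblast cluster led by Saa1, Lcn2 and Saa3 that held 4.09% or less elsewhere. Because genes that define these fibroblast classes themselves differed with Spn, their shares are descriptions of cluster membership. Mesothelial-like cells were at 0.753 ± 0.043% with Spn against 0.354 ± 0.134% (exact p = 0.1) and proliferating cells at 0.547 ± 0.294% against 0.229 ± 0.210% (exact p = 0.2). Cells of the mixed immune cluster, most of which held Col1a2, were at 1.85 ± 0.570% against 1.29 ± 0.215% (exact p = 0.2). Alveolar epithelial-like cells were at 0.147 ± 0.102% against 0.285 ± 0.083% (exact p = 0.3). Smooth muscle-like cells were at 1.12 ± 0.232% against 1.06 ± 0.223% (exact p = 0.9), and unnamed fibroblasts at 65.0 ± 5.003% against 55.3 ± 3.76% (exact p = 0.1; all SD, n = 3). All fibroblast-like cells together were at 95.6 ± 0.749% against 96.7 ± 0.688% (exact p = 0.2). Leaving out 1 library moved the smaller differences. That of the mixed immune cluster (0.552 percentage points) ranged from 0.233 to 0.782, of alveolar epithelial-like cells (-0.139) from -0.189 to -0.087 and of proliferating cells (0.318) from 0.221 to 0.487. That of smooth muscle-like cells (0.060) ranged from -0.068 to 0.158, and that of all fibroblast-like cells (-1.17) from -1.50 to -0.764. The alveolar (-15.6 to -9.23) and fibrotic (-5.70 to -4.82) fibroblast-like differences kept their direction when 1 library was left out. The alveolar one did not keep it within sample 2 of day 21 at resolution 0.5. The 10 tests were 2-sided, and 0.1 is the smallest p that 3 libraries against 3 can give. The PDGFRα sort sets the share of each cell type that could be seen.

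**Figure D3:**
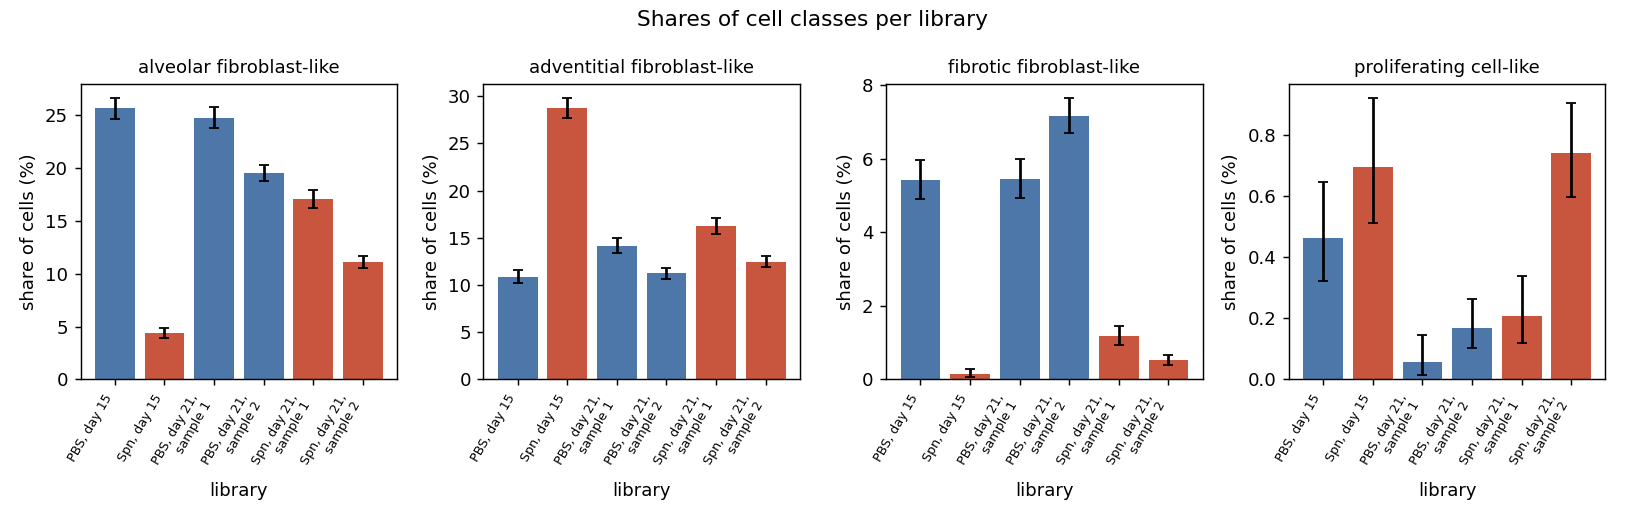
Bars give the percentage of called cells in each library assigned to alveolar, adventitial and fibrotic fibroblast-like and proliferating clusters, with PBS libraries in blue, Spn libraries in red and exact 95% binomial intervals. Fibrotic fibroblast-like cells lie between 5.42% and 7.17% in the PBS libraries and between 0.147% and 1.17% in the Spn libraries.

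Within alveolar fibroblast-like cells, 40 genes rose and 7 fell with Spn over both days in edgeR, which called 0 in the whole fibroblast-like population, where DESeq2 called 256. Haptoglobin (Hp), an acute phase haemoglobin scavenger, had the smallest p and rose from 122 to 1123 CPM at day 15 and from 36.9 and 43.0 to 161 and 421 CPM at day 21. Its log2 fold change was 2.97 ± 0.28 (SE, n = 3 per group, edgeR adjusted p = 6.0e-04). Rnd1 (1.69 ± 0.17), Lcn2 (4.92 ± 0.54), Ifi205 (2.57 ± 0.28), Saa1 (3.91 ± 0.43) and Saa3 (4.17 ± 0.47) were higher, with edgeR adjusted p-values up to 0.00106. At day 15 Saa3 of these cells stood at 2.855% of its level in low-UMI barcodes, where Igkc allows a share of free RNA of 1.509%, so free RNA was not ruled out there. The risen genes also held the interferon and antigen presentation genes Tap1 (1.04 ± 0.18), Gbp6 (1.29 ± 0.17) and H2-K1 (0.89 ± 0.16). The chemokine gene Cxcl10 (1.14 ± 0.22) and Rspo3 (1.86 ± 0.25) rose as well. The acetylcholinesterase anchor gene Colq (-1.25 ± 0.20), Kcnk2 (-0.94 ± 0.16), Bhlhe40 (-0.80 ± 0.14), Mustn1 (-0.99 ± 0.19) and Syn3 (-0.61 ± 0.11) fell. Col1a1 (-0.13 ± 0.16) and Pdgfra (-0.03 ± 0.15) did not pass (edgeR adjusted p = 0.982 and 1.00). Of 12655 genes tested, 831 had an unadjusted p under 0.05. Genes that define this class themselves fell with Spn at day 15, so the test covers only cells that kept them. The 47 calls became 84 without Spn sample 1, 5 without Spn sample 2 and 22 without PBS sample 2 of day 21. Igkc (2.08 ± 0.40) and Mpeg1 (2.94 ± 0.58), genes of B cells and macrophages, were among those that rose.

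Within adventitial fibroblast-like cells, 12 genes rose and 1 fell. Saa3 rose from 384 to 40512 CPM at day 15 and from 117 and 150 to 2397 and 12971 CPM at day 21. Its log2 fold change was 6.27 ± 0.70 (SE, n = 3 per group, edgeR adjusted p = 0.0294). With it rose Rnd1 (2.51 ± 0.19), Lcn2 (7.79 ± 1.01), Csf3 (7.32 ± 0.88), Saa4 (8.91 ± 0.79), Cxcl2 (2.60 ± 0.34), H2-Q6 (2.18 ± 0.25) and H2-Q7 (1.97 ± 0.26). So did Ifi202b (11.5 ± 0.63), found in the day 15 Spn library, the sphingosine-1-phosphate receptor gene S1pr3 (1.41 ± 0.17), Nrep (1.32 ± 0.17) and Csf2rb (2.49 ± 0.34). The carbonic anhydrase gene Car3 fell (-7.57 ± 0.76, edgeR adjusted p = 0.0201). Of 12251 genes tested, 1548 had an unadjusted p under 0.05. The day 15 Spn cells of this class came mostly from a cluster of their own, named on 4 of 10 adventitial markers. Without either library of day 15 the Spn effect rests on day 21 alone. The 13 calls became 296 without Spn sample 1 and 4 without Spn sample 2 of day 21, 4 without the PBS and 4 without the Spn library of day 15, and 0 and 2 without PBS samples 1 and 2 of day 21.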

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

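The tests of a day by Spn difference, of genotype, of free RNA and of immunoglobulin UMIs in this part were chosen after the results were seen.

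The Spn effect at day 21 differed from that at day 15 for some of the named genes in an edgeR test of the difference. No gene list was tested for it. Of 15678 genes tested, 2122 passed (993 with a more positive and 1129 with a more negative effect at day 21), 4842 had an unadjusted p under 0.05, and DESeq2 called 1864. The test takes its spread from the day 21 replicates alone and assumes that the lone day 15 libraries vary alike. Day cannot be told apart from a library batch, nor from a possible mix of genotypes in the day 15 Spn library, described below. Among the named genes, 37 that passed are given here, with edgeR adjusted p-values from 0.00164 (Cpm) to 0.0466 (Saa1). Of these, 13 had the largest or smallest ratios of day 15, which favours a difference. Log2 differences below 0, that is a less positive effect at day 21, were found for the acute phase and innate genes Ptx3 (-5.705), Serpina3m (-4.760), Saa1 (-4.743), Cfb (-3.277), Sod2 (-2.579), Irak3 (-0.993) and Ccl11 (-1.403), for the interferon and antigen presentation genes Rsad2 (-4.251), Ifi44 (-3.516), Ifi205 (-3.401), Gbp4 (-1.831), Nlrc5 (-1.549) and Tap1 (-1.522), and for Ly6a (-3.603), Plac8 (-2.809), Pf4 (-2.796), Rnd1 (-1.203) and Sdf2l1 (-1.030). Differences above 0 were found for alveolar fibroblast genes and others: Cpm (3.961), Scn3a (2.737), Scube2 (2.558), Itga8 (2.450), Mamdc2 (2.361), Thbd (2.170), Pcolce2 (2.136), Nnat (2.111), St8sia2 (2.023), Tagln (1.976), Slc38a5 (1.622), Cthrc1 (1.527), Syn3 (1.470), Mfap4 (1.393), Postn (1.172), Inmt (1.151), Kcnk2 (1.077), Fgf10 (1.026) and Mustn1 (0.818). For Saa3 (-3.36 ± 1.13, edgeR adjusted p = 0.0942) and Lcn2 (-2.58, 0.229) the difference did not pass.

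Other results moved one way at day 15 and the other way in both day 21 pairs, and apart from Pdgfra and Cthrc1 these differences were not tested. Ratios here are on TMM-scaled CPM. The median log2 ratio of the myofibroblast and fibrotic fibroblast list was -0.325 at day 15 against 0.294 and 0.121 at day 21, that of the hypoxia and glycolysis list 0.798 against -0.063 and -0.022, and the log2 ratio of Pdgfra 0.026 against -0.218 and -0.040. Without TMM factors the day 15 medians of these lists were -0.75 and 0.37, and Pdgfra was lower at day 15 too (452 against 596 CPM), so its change of direction rests on the scaling. The edgeR test of its difference did not pass (-0.157 ± 0.233, adjusted p = 0.679). Cthrc1, whose difference passed above, was at -0.493 against 1.092 and 0.997. In percentage points, Spn less PBS, the share of the mixed immune cluster was -0.138 against 0.410 and 1.385, of smooth muscle-like cells -0.255 against 0.181 and 0.255, and of all fibroblast-like cells 0.146 against -0.955 and -2.701.

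In the barcodes with 1 to 100 UMIs, which no comparison uses, macrophage and monocyte marker UMIs were 2.595-fold and lymphocyte marker UMIs 3.228-fold as frequent in the mean Spn library as in the mean PBS library, with each Spn library above the PBS libraries of its day. Single libraries carried these means. Macrophage and monocyte markers were at 1928 against 382 CPM at day 15, and at 500 and 754 against 456 and 387 CPM at day 21. Their list contains Plac8, which fibroblast-like cells held at 229 and 477 CPM with Spn at day 21, so it does not speak for macrophages alone. Lymphocyte markers were at 574 against 57.4 CPM at day 15, and at 1952 and 1430 against 173 and 995 CPM at day 21. Neutrophil markers were 5.453-fold as frequent, but Spn sample 1 of day 21 (1282 CPM) lay below PBS sample 1 (1299 CPM). Lcn2, which fibroblast-like cells also expressed, made up 17414 of the 17821 CPM of this list in the day 15 Spn library. The ratio therefore rests mostly on Lcn2 and does not speak for neutrophils. Alveolar epithelial markers were 0.4049-fold as frequent and lower in each Spn library than in the PBS libraries of its day.

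Ifi202b and 2 copies of Rps18, a ribosomal protein gene, were counted almost only in the day 15 Spn library. Ifi202b (chromosome 1, 173962568 to 173982744) had 6630 UMIs there, 2 in Spn sample 2 of day 21 and 0 in the other libraries, and its expression is known to differ between inbred mouse strains. If interferon induced Ifi202b alike in all mice, the excess of Ifi205 in that day 21 library would call for 474.2 Ifi202b UMIs. The 2 seen are 0.4218% of that. This cannot decide on induction in the day 15 Spn cells, because day 21 mice of a strain without Ifi202b expression would show none. In the largest cluster of the day 15 Spn library, 57 cells held both Ifi202b and an Rps18 copy, 27.42% of the 207.9 that independence gives within depth bins. Cells with 2 or more UMIs of the copies and none of Ifi202b were set against cells with 2 or more UMIs of Ifi202b and none of the copies. Rps18 alone stood at 61.76% of the level in the Ifi202b cells, and Rps18 plus its copies at 94.52%. Choosing cells by UMIs of the copies raises that sum, so the sum cannot decide whether Rps18 reads were counted at the copies. Cells of mice of differing genotype in that library, with Rps18 reads counted at its copies in some of them, are a candidate explanation, which remains a hypothesis. A mixed or mislabelled sample stays open.

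Saa3 in the day 15 Spn library was weighed against that mixture and against free RNA. Cells with the Rps18 copies and without Ifi202b held Saa3 at 201.4-fold its level in the day 15 PBS library. Cells with Ifi202b and without the copies held it at 274.8-fold, so Saa3 was not carried by only 1 of these sets. The day 15 PBS library held 0 UMIs of Ifi202b and 14 and 36 of the copies. Because the sets were formed by UMIs of these genes, neither set could resemble that library, and other cells were left out. A difference of genotype between the libraries was thus not tested and cannot be told apart from an effect of Spn. In fibroblast-like cells Saa3 stood at 101.6% of its level in low-UMI barcodes, while Scgb1a1 of airway cells allows a share of free RNA of 2.81%, which argues against free RNA. In alveolar fibroblast-like cells Saa3 needs 2.855% against the 1.509% that Igkc allows, so cells with their own Saa3 and free RNA cannot be told apart there, because the margin is under 3-fold. The bound was first the highest share over 5 genes and was changed to the lowest over Igkc, Sftpc and Scgb1a1 after its values were seen, which moved the alveolar result from favouring free RNA and left the other.

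Immunoglobulin UMIs in fibroblast-like cells at day 21 lay in few cells. In the Spn libraries, the 1% of cells with the most Igkc held 80.21% and 67.40% of its UMIs, and 80% and 83.6% in the PBS libraries, which argues against free RNA spread over all cells. Fibroblasts joined with an immune cell are a candidate explanation for these UMIs, given that called doublets were almost absent. This test replaced a first one, a ratio of cells to low-UMI barcodes that had favoured free RNA, after the first was seen.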

How the results depend on the processing

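Removing the highest 8% of doublet scores was chosen after the data were seen. Of the alternatives to the values that answer a comparison, 167 left a value on its side of the threshold or within its spread and 48 did not. Of those for named genes, 1889 left direction and call, 203 made a call where there was none, 1 ended the call of Rnd1 at day 21 (no low-count filter, edgeR adjusted p = 0.0697), and 5 reversed a direction. Unless the construction shows it, the cause was not tested.

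The day 21 count of 1 gene became 203 with DESeq2, 2 with RLE factors, 0 without the filter (edgeR, 1111 genes at an unadjusted p under 0.05 with it), 55 with the sample number as a block, 2 at a mitochondrial share of 5%, 3 with cells by detected genes, 3 with all called cells, 2 without the highest 8% of doublet scores, and 4 (without PBS sample 2) to 339 (without Spn sample 1) with 1 library left out. The count of 0 over both days (edgeR, 1685 unadjusted) became 256 with DESeq2, 2 without the filter, 1 with the block, 1 with all called cells, and 0 to 56 (without Spn sample 1 of day 21). For day 21 against day 15, 3 became 137 with DESeq2, 5 without the filter, 1 with cells by detected genes, 1 with all called cells, 1 without the highest doublet scores, and 0 (without the Spn library of day 15, or Spn sample 2) to 5293 (without the PBS library of day 15). Pairing is not established by the labels. The residuals of the day 21 pairs correlated at 0.20. With 2 libraries per group the residuals of both pairs mirror each other, so this is a single value and cannot establish pairing. The block gave 11 lists at day 21 and 14 over both days.

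Saa3 over both days passed with DESeq2 (5.9233) and without Spn sample 1 of day 21 (6.8186), and leaving out 1 library gave 4.9058 to 6.8186. With an estimated correlation 0 lists passed at day 21 and 0 over both days, and leaving out 1 library gave 8 (without PBS sample 1) to 14 lists at day 21. Within alveolar cells 47 genes became 290 without the filter and 5 (without Spn sample 2 of day 21) to 84 (without Spn sample 1) with 1 library left out. Within adventitial cells 13 became 850 without the filter and 0 (without PBS sample 1 of day 21) to 296 (without Spn sample 1). At day 15, a CPM minimum of 50 in place of 20, which compares fewer genes, gave 782 2-fold genes in place of 1319.

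At resolution 0.5 the adventitial share difference was -1.314 in place of 7.04 percentage points and the fibrotic one -3.966 in place of -5.40. The alveolar share in sample 2 of day 21 was higher with Spn at that resolution and lower at resolution 1. Acta2 at day 21 (0.02) was -0.1463 without PBS sample 1, -0.2854 without Spn sample 2 and -0.0023 without the highest doublet scores, and over both days (-0.34) it was 0.0206 without the PBS and 0.0222 without the Spn library of day 15, never past the threshold, with ranges over 1 library left out of -0.2854 to 0.2738 and -0.618 to 0.0222. In a left-out fit the lone library of an arm is assumed to vary like the others. Over both days, a fit without either library of day 15 takes its Spn effect from day 21 alone. Depth limits genes of low CPM, since each library sum held 35931437 to 46879027 UMIs.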

Other observations

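The tests of positions near Rps18 in this part were chosen after the results were seen, and the counts of other splits were set before. Saa3 differed between the clustered cell classes in each Spn library. At day 21 it reached 3976 and 29554 CPM in mesothelial-like cells, 2397 and 12971 CPM in adventitial, 1422 and 5223 CPM in unnamed and 107 and 361 CPM in alveolar fibroblast-like cells. The chemokine gene Cxcl13 reached 401 and 2340 CPM in adventitial and 2.59 and 3.79 CPM in alveolar fibroblast-like cells, and Timp1, an inhibitor of matrix proteases, 406 and 1013 against 64.0 and 95.1 CPM. Haptoglobin was arranged otherwise, with 45.5 and 238 CPM in adventitial, 161 and 421 CPM in alveolar and 397 and 1057 CPM in unnamed fibroblast-like cells. At day 15 with Spn, Saa3 stood at 70191 CPM in unnamed, 40512 CPM in adventitial and 1713 CPM in alveolar fibroblast-like cells, the last being 297 cells. Alveolar fibroblast genes themselves fell with Spn at day 15, so cells that lost them may lie in the unnamed class. The day 15 values of the fibroblast classes thus describe cluster membership.

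Genes that differed between both sets of cells of the day 15 Spn library lay near Rps18 (chromosome 17, 33951999 to 33956001) more often than others. Within 5 Mb lay 6.82% of 220 differing genes against 1.51% of the rest (odds ratio 4.76), and without the H2, Tap and Psmb genes, which interferon also moves, 3.76% against 1.25% (odds ratio 3.07). Both counts include Rps18 itself, at 727.6 CPM in the cells with copies against 1178 CPM in those with Ifi202b. The sets were formed by UMIs of its copies, so this gene is not independent of them.

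With 10 splits of 6 libraries into 3 and 3, the splits are too few for a share under 0.05. Over both days the real split gave 0 genes (edgeR, 1685 at an unadjusted p under 0.05, 256 by DESeq2) and the highest other split 0, so 10 of 10 splits gave as many. A real count of 0 fixes this outcome, so it decides nothing. For lists it gave 15 and the highest other split 15, so 2 of 10 gave as many, the other one setting PBS of day 15, Spn sample 1 and PBS sample 2 of day 21 against the rest. Within alveolar fibroblast-like cells it gave 47 genes and the highest other split 2, so 1 of 10 gave as many, and within adventitial fibroblast-like cells 13 genes and 0, so 1 of 10 gave as many.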
